A study of Sus scrofa with 10 samples.

How the data were processed

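Liver RNA of male pigs was measured by RNA sequencing in 10 samples, with 5 labelled high and 5 labelled low for growth and fatness. Per the labels' protocols, the tissue was taken at slaughter and frozen in liquid nitrogen, RNA integrity numbers lay between 7.1 and 8.1, and TruSeq v2 libraries with fragments of 300 bp were sequenced in paired reads of 75 bp on an Illumina HiSeq, with 3 samples per lane. Which samples shared a lane is not given in the sources used here. This library kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The pig genome build was Sscrofa10.2, per the submitters' processing notes, and the aligner, the counting tool and the annotation release are not given in the sources used here.

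The authors deposited 1 table of 25009 Ensembl gene identifiers with an RPKM value (read density scaled to gene length and to the mapped reads of the library) for each library, per the file headers. In the deposited RPKM columns 624 values of 1000 or more, in 92 genes, carried a dot as a digit-group mark and were read accordingly. The deposited table also held the authors' signed fold change and the authors' p-value for each gene. In 96.7% of the tested genes with a fold other than 1, a positive fold in the authors' table went with a higher mean log2(RPKM + 1) in the low group and a negative fold with a higher mean in the high group. In 440 genes the fold differed from 1 although the RPKM was 0 in every library. What the fold was computed from and the test behind the p-value are not stated in the file headers.

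The choice of tests, gene lists, named genes and most alternatives was fixed before the data were examined, for counts or for normalized values. The deposited values were not counts, so the count tests in that plan did not apply and the plan for normalized values was used. Values were analysed as log2(RPKM + 1), a scale that understates the change of genes with low values. Genes with a mean of at least 1 RPKM over all 10 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, high minus low), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All 10 libraries entered the fit without covariates. Replicate numbers only name the samples and pair nothing. The labels do not say whether each sample came from a separate animal, so p-values measure the spread between these samples.

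The absolute depth of the libraries is unknown. Relative depth was read from the steps of values under 0.01 RPKM, where the most common ratio between libraries reflects what 1 read is worth. In 36 of 36 pairs of the other libraries the estimates closed within 1%, although some rested on as few as 4 genes. Because whole reads could not be recovered from RPKM without gene lengths, no counting interval is given.

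Symbols came from a table of identifiers and names, which matched 11779 of the 25009 identifiers and 7224 of the 10931 genes tested. No gene coordinates were used here, since the annotation at hand was of another build. There were 29 gene lists, for liver metabolism, growth, stress, immune response and the other cell types a piece of liver can hold. List symbols renamed since were matched through a short table of current names written after the data were seen, and a symbol carried by more than 1 identifier (GZMA) took each of them. The 22 lists with at least 5 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), and again with an estimated correlation and with fry. Lists of 42 brain genes (30 matched by name) and 10 peripheral nerve genes (6 matched) were written after 21 genes of the pattern had been seen. The level of a cell type was the mean log2(RPKM + 1) of its listed genes above 0, and levels were compared by an exact two-sided permutation test over 252 assignments, whose smallest p is 0.00794. Correlations across libraries were tested with 100000 permutations.

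The genes named in the text were chosen by a rule fixed in advance. Its first part was the 12 genes per direction with a symbol and the smallest p among those past the threshold, filled up to 6 per direction by smallest p where fewer passed. The second part was 12 genes taken whatever their result, among them IGF1, GHR, IGFBP2, SREBF1, FASN, SCD, PPARA, CPT1A, CYP7A1, PCK1 and LEPR, of which IGFBP2 and SREBF1 had no identifier matched by name and are not analysed here. The third part was up to 4 members with the smallest p in each list described. Some genes that the rule named are not reported here, and no others took their place. Other genes are said to have been chosen after their values were seen.

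The fit was tested on simulated data with 200 changed genes in each of 10 runs, drawn with the observed means and independent Gaussian residuals over 10931 genes. For the comparison of high with low it called 40.6% of 1.5-fold, 75.8% of 2-fold, 91.2% of 3-fold and 94.8% of 4-fold changes, with 7.4 false calls per run. These are folds of RPKM + 1. For genes with low values the same fold of RPKM is a smaller change on this scale, so the shares do not hold for it. The shares also depend on the 200 changed genes. Where fewer genes change, the Benjamini-Hochberg threshold asks for a smaller p, so fewer of them would be called. A lack of calls in the real data therefore does not exclude changes of these sizes in a few genes. The simulation held no correlation between genes, which the real libraries have. Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 RPKM, median scaling, quantile normalization, thresholds of 0.1 and 0.01, a minimum fold of 1.5, and leaving out each library in turn. A covariate from the residuals, and a fit without high replicates 1 and 5, were added after the data were seen.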

Results

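Liver samples of pigs, 5 labelled high and 5 labelled low for growth and fatness, were compared, all male and all with an age label of 175 whose unit is not given. The RPKM values summed to between 539327 and 567220 per library, and 16195 to 16802 genes had a value above 0. Relative depth ran from 0.748 to 1.05 of that of high replicate 1, a 1.41-fold range, and the absolute depth is unknown. The 10 largest genes held 27.1% to 33.6% of the summed RPKM. The 13 protein-coding genes of the mitochondrial genome held 10.1% to 20.2%, with the highest share in low replicate 4. Pairwise Pearson correlations of log2(RPKM + 1) across genes, which are not independent replicates, lay between 0.906 and 0.99, and the closest pair, high replicates 2 and 4, had identical values in 0.595% of the tested genes.

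The comparison of high with low asked which liver transcripts differ between pigs that diverge in growth and fatness. No gene passed the threshold, so the genes named first are those with the smallest p and did not pass. GPT2 (ENSSSCG00000002847), the mitochondrial alanine aminotransferase, had a mean of 57.7 ± 19.1 RPKM in high and 22.5 ± 5.38 in low (SD, n = 5 each). The F-box gene FBXO39 (ENSSSCG00000017886) had 4.89 ± 0.911 RPKM in high and 10.5 ± 3.91 in low. Of 10931 genes, 0 had an adjusted p under 0.05 in limma, the smallest adjusted p was 0.962, and 497 genes had an unadjusted p under 0.05, 248 with the higher mean in high and 249 with the higher mean in low. That share was 4.55%, where chance gives 5%.

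GPT2 had a log2 fold change of 1.28 (SE 0.25) and the values of the groups did not overlap. The other 5 genes with the higher mean in high differed less. UBXN4 (ENSSSCG00000015690), which takes part in the degradation of proteins of the endoplasmic reticulum, had 69.8 ± 3.18 RPKM in high and 53.2 ± 3.50 in low. POMT2 (ENSSSCG00000002397), a protein O-mannosyltransferase, had 2.47 ± 0.107 and 1.56 ± 0.209 RPKM. The ubiquitin ligase gene COP1 (ENSSSCG00000015509) had 4.90 ± 0.670 and 3.27 ± 0.423 RPKM. UACA (ENSSSCG00000004973) had means of 9.59 and 6.81 RPKM and SH3D19 (ENSSSCG00000009018) had 19.6 and 14.2 RPKM. On the log2 scale these 5 genes differed by 0.39 to 0.47.

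Among the genes with the higher mean in low, FBXO39 had a log2 fold change of -0.93 (SE 0.20). ARL2BP (ENSSSCG00000002819), which binds the small GTPase ARL2, had 11.2 ± 4.65 RPKM in high and 22.8 ± 9.30 in low, and its groups overlapped. The sugar transporter gene SLC50A1 (ENSSSCG00000006529) had 6.70 ± 0.649 and 9.39 ± 1.19 RPKM. ERMARD (ENSSSCG00000004010) had means of 2.04 and 2.81 RPKM, and CTRL (ENSSSCG00000023849), which encodes a chymotrypsin-like protease, had 0.696 and 1.41 RPKM. In all, 88 of the tested genes had groups that did not overlap, which is 0.805%, where chance gives 0.794%.

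The genes of growth and lipid metabolism chosen in advance did not pass either. IGF1 (ENSSSCG00000000857), the liver-made growth factor, had 14.6 ± 5.5 RPKM in high and 10.4 ± 5.79 in low, and the growth hormone receptor gene GHR (ENSSSCG00000016866) had 44.9 ± 13.0 and 31.9 ± 11.95 RPKM. PPARA (ENSSSCG00000000006), a regulator of fatty acid oxidation, had 31.4 ± 5.52 and 21.8 ± 6.92 RPKM, with an adjusted p of 0.962 in limma. CPT1A (ENSSSCG00000012880), which brings fatty acids into mitochondria, had 106 ± 33.9 and 79.9 ± 24.4 RPKM. The fatty acid synthase gene FASN (ENSSSCG00000029944) had 2.81 ± 0.560 and 2.99 ± 1.55 RPKM, and the desaturase gene SCD (ENSSSCG00000010554) had 2.94 ± 0.834 and 4.28 ± 2.23 RPKM. CYP7A1 (ENSSSCG00000006238), the rate-limiting enzyme of bile acid synthesis, had 0.868 ± 1.25 and 4.14 ± 4.93 RPKM. PCK1 (ENSSSCG00000007507), an enzyme of gluconeogenesis, had 489 ± 259 and 456 ± 167 RPKM. The leptin receptor gene LEPR (ENSSSCG00000025188) had 20.4 ± 25.6 and 10.1 ± 16.2 RPKM, with 37.7, 57.0 and 39.1 RPKM in high replicates 1 and 4 and low replicate 4 and at most 4.35 RPKM in the other libraries.

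**Figure D1:**
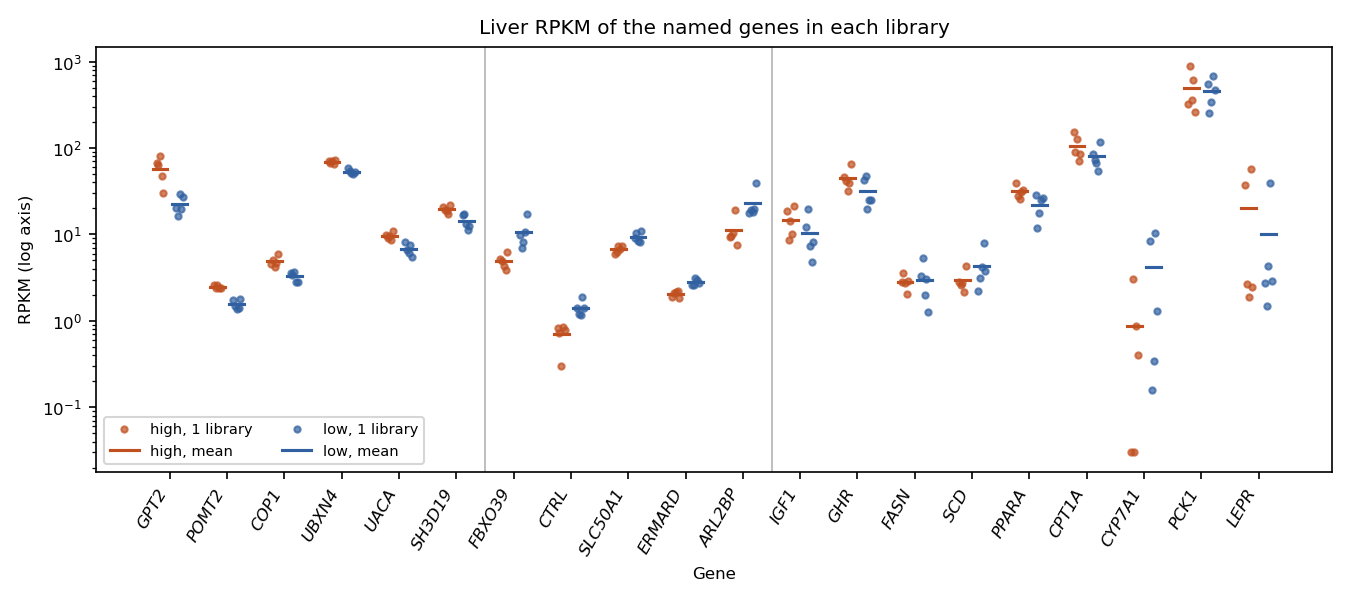
RPKM on a log axis (vertical) of 20 genes (horizontal), with 1 point per library and a bar at the mean of each group. The first 6 genes had the higher mean in high and the next 5 the higher mean in low, and the rest were chosen in advance; GPT2 averaged 57.7 RPKM in high and 22.5 in low.

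The heat shock and unfolded protein response list had the higher mean in high. Of its 18 tested members 15 had a positive log2 fold change, and their mean was 0.30. HSPA5, the main chaperone of the endoplasmic reticulum, had 751 ± 314 RPKM in high and 453 ± 183 in low, and HYOU1, which works with it, had 137 ± 62.1 and 76.4 ± 29.3 RPKM. Both had their highest values in high replicates 1 and 3 (1057 and 1060 RPKM for HSPA5, 205 and 193 for HYOU1). Both had their lowest in low replicate 4 (148 and 31.1 RPKM). High replicates 1 and 3 lay at one end of the first principal component and low replicate 4 at the other end. Low replicate 2 lay at the same end as high replicates 1 and 3, with 509 RPKM for HSPA5 and 106 for HYOU1. High replicate 5, between the ends, had more (762 and 132 RPKM). In high replicate 2, with 377 RPKM for HSPA5 and 63.7 for HYOU1, both lay below 4 of the 5 low libraries. DNAJB9 had 94.9 ± 18.1 and 65.9 ± 13.3 RPKM, and the constitutive chaperone gene HSPA8 had 359 ± 16.4 and 284 ± 61.9 RPKM. The list passed camera with the preset correlation (adjusted p = 0.000366, limma) and did not pass otherwise (adjusted p = 0.896 with an estimated correlation, adjusted p = 0.897 with fry). The estimated correlation between its members was 0.409, far above the preset 0.01, so the preset setting gave too small a p for this list. No member passed over all genes, and 0 passed adjusted over the list alone, with 2 members at an unadjusted p under 0.05 in limma. Without low replicate 4 the mean log2 fold change was 0.13 and the list did not pass (adjusted p = 0.0667 with camera).

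The T and NK cell list had the higher mean in low, with 9 of 9 tested members in that direction and a mean log2 fold change of -0.45. The T cell kinase gene LCK had 1.66 ± 0.479 RPKM in high and 3.22 ± 1.45 in low. CD8A, a coreceptor of cytotoxic T cells, had 1.67 ± 0.938 and 3.58 ± 2.27 RPKM, and CD247, a chain of the T cell receptor complex, had 9.48 ± 3.90 and 13.9 ± 2.35 RPKM. CD2 had 2.13 ± 0.867 and 3.33 ± 1.46 RPKM. The list passed camera with the preset correlation (adjusted p = 0.000366, limma) and did not pass otherwise (adjusted p = 0.896 with an estimated correlation, adjusted p = 0.897 with fry). The estimated correlation between its members was 0.608, far above the preset 0.01, so here too the preset setting gave too small a p. Over all genes 0 members passed, and 0 passed adjusted over the list alone, with 3 members at an unadjusted p under 0.05 in limma. GZMA is carried by 2 identifiers of neighbouring number, between which reads could be split.

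None of the lists of lipid metabolism passed. In the list of cholesterol synthesis and uptake 14 of 21 members had the higher mean in low (adjusted p = 0.358 with camera), among them FDPS at 28.8 ± 9.83 RPKM in high and 42.5 ± 13.8 in low, and IDI1 at 39.2 ± 20.3 and 67.4 ± 32.3. The lipoprotein list had 10 of 14 in that direction (adjusted p = 0.358), with the apolipoprotein gene APOA2 at 652 ± 271 and 1270 ± 547 RPKM and APOM at 92.3 ± 23.7 and 126 ± 21.8. The list of fatty acid and triglyceride synthesis had 13 of 18 in that direction (adjusted p = 0.508), with FADS1 at 5.13 ± 2.04 and 12.3 ± 12.4 RPKM. Fatty acid oxidation and ketogenesis had 15 of 26 with the higher mean in high (adjusted p = 0.358), with ACADVL at 50.2 ± 11.5 and 38.4 ± 14.9 RPKM. Bile acid synthesis and transport had 6 of 11 with the higher mean in low (adjusted p = 0.726). In each of these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. The cholesterol list passed camera without high replicate 5 (adjusted p = 0.0440) or low replicate 1 (adjusted p = 0.0159), and the oxidation list without high replicate 3 (adjusted p = 0.0196) or low replicate 5 (adjusted p = 0.0178). With an estimated correlation neither passed camera, in the same fits (adjusted p = 0.911 to 0.963) or with all libraries (adjusted p = 0.896).

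The lists of growth, glucose and amino acids did not pass either. The growth hormone and IGF list had 6 members in each direction (adjusted p = 0.726), with IGFBP1, a binding protein of the insulin-like growth factors, at 74.8 ± 40.5 RPKM in high and 174 ± 123 in low. The glucose and glycogen list had 10 of 18 with the higher mean in low (adjusted p = 0.726), and its mean and median were negative, while camera gave the opposite direction. Amino acid breakdown and the urea cycle had 16 of 23 with the higher mean in high (adjusted p = 0.703), with the lysine-degrading enzyme AASS at 36.6 ± 5.71 and 24.8 ± 9.26 RPKM and the kynurenine monooxygenase gene KMO at 58.4 ± 16.1 and 82.1 ± 18.5. The nuclear genes of the respiratory chain had 12 of 20 with the higher mean in high (adjusted p = 0.358), with UQCRC2 at 41.0 ± 7.60 and 30.7 ± 8.57 RPKM. The xenobiotic and steroid list had 9 of 14 with the higher mean in low (adjusted p = 0.703). In each of these 5 lists 0 members passed over all genes and 0 adjusted over the list alone.

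Among the remaining lists, the acute phase list had 11 of 15 members with the higher mean in high (adjusted p = 0.276), with the complement gene C3 at 1091 ± 175 RPKM in high and 845 ± 305 in low. The interferon list had 13 of 22 with the higher mean in low (adjusted p = 0.423), with IRF7 at 2.27 ± 0.499 and 4.32 ± 2.40 RPKM. It passed camera without high replicate 5 (adjusted p = 0.0117), low replicate 4 (adjusted p = 0.000811) or both high replicates 1 and 5 (adjusted p = 0.0191). With an estimated correlation it did not pass camera, in the same fits (adjusted p = 0.922 to 0.998) or with all libraries (adjusted p = 0.896). The circadian clock list had an adjusted p of 0.703. The extracellular matrix list had an adjusted p of 0.586, with BGN at 56.2 ± 8.60 and 71.7 ± 11.0 RPKM. The immediate early list had an adjusted p of 0.743, with DUSP1 at 38.9 ± 4.69 and 52.6 ± 11.1 RPKM, and its mean was positive while its median and test were negative. In each of these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. Of the cell cycle list only CDC20 was tested (1.14 ± 0.269 and 1.71 ± 0.40 RPKM), which passed adjusted over the list alone because a list of 1 gene needs no adjustment, and did not pass over all genes.

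**Figure D2:**
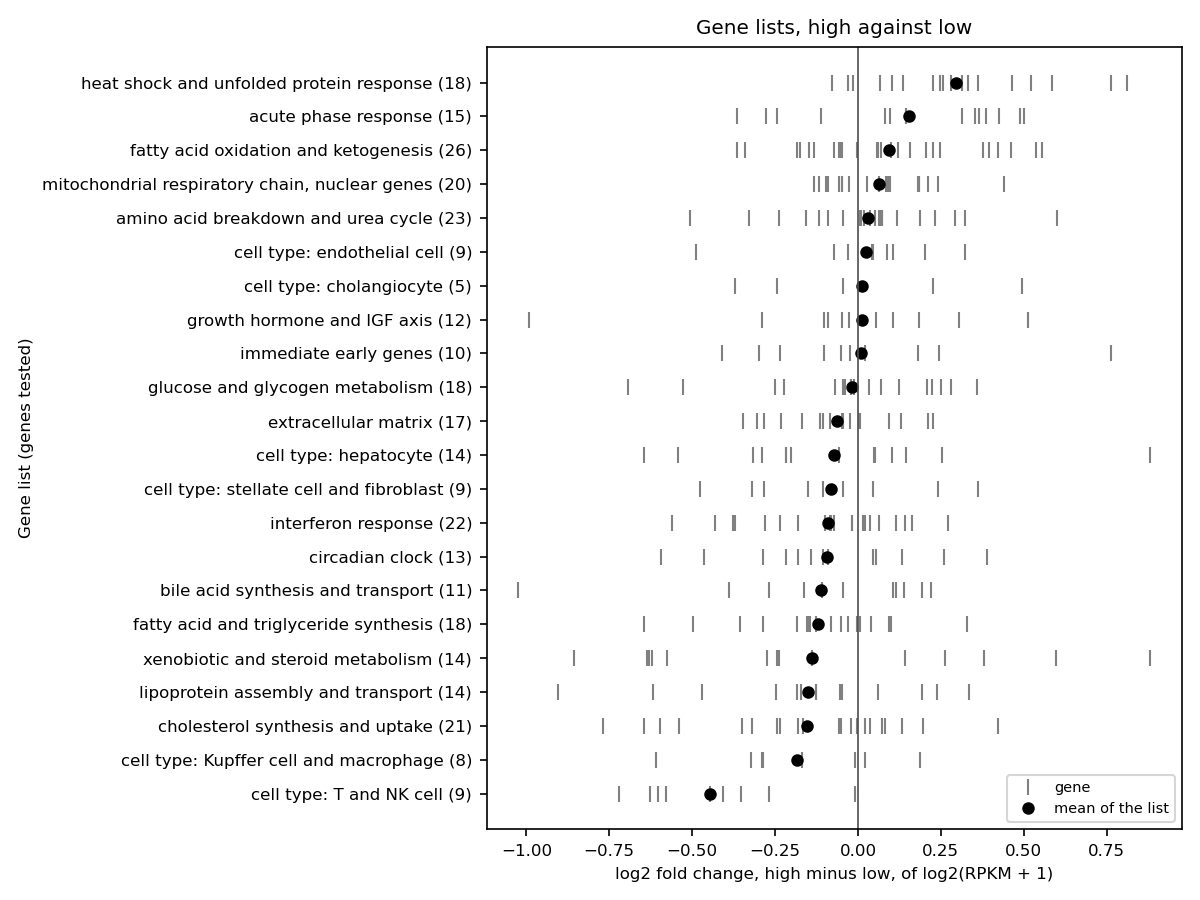
Log2 fold change, high minus low, of log2(RPKM + 1) (horizontal) for each gene of the 22 tested lists (vertical, number of tested genes in brackets), with a dot at the mean of each list. The heat shock and unfolded protein response list had a mean of 0.30 and the T and NK cell list a mean of -0.45; neither passed with an estimated correlation.

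Markers of the cell types a piece of liver can hold were compared as levels per library. The hepatocyte level was 10.0 ± 0.345 in high and 10.1 ± 0.236 in low (mean log2(RPKM + 1) ± SD, n = 5 each), with an exact permutation p of 0.675. The T and NK cell level was 1.90 ± 0.243 and 2.25 ± 0.413, with an exact permutation p of 0.143, the smallest of the 17 measures compared (adjusted p = 0.638). For B and plasma cells the exact permutation p was 0.167 (0.0476 without low replicate 5), for muscle 0.302, for Kupffer cells and macrophages 0.325, for adipocytes 0.341, for exocrine pancreas and gut 0.365 and for red blood cells 0.405. It was 0.516 for neutrophils, 0.627 for stellate cells and fibroblasts, 0.857 for cholangiocytes and 0.905 for endothelial cells. Relative depth had an exact permutation p of 0.238, the number of genes above 0 had 0.175, the mitochondrial share had 0.413, the share of the 10 largest genes had 0.381 and the summed RPKM had 0.492.

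With camera the other cell type lists with enough members did not pass. The Kupffer cell and macrophage list had an adjusted p of 0.358, with the complement gene C1QA at 171 ± 14.3 RPKM in high and 219 ± 58.1 in low. The hepatocyte list had an adjusted p of 0.586, with CYP2E1 at 1031 ± 267 and 794 ± 584 RPKM and TTR at 2055 ± 1154 and 3025 ± 1569. The adjusted p was 0.726 for the endothelial list and for the stellate cell and fibroblast list, in which RELN had 4.89 ± 1.55 and 3.49 ± 0.377 RPKM. It was 0.998 for the cholangiocyte list, whose mean was positive while its median and test were negative. The B and plasma cell, adipocyte, exocrine pancreas and gut, muscle, neutrophil and red blood cell lists had too few tested members. In these lists 0 members passed over all genes and 0 adjusted over the list alone.

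Transcripts of the nervous system were present in high replicates 1 and 5. GFAP, the intermediate filament of astrocytes, had 3.66 and 4.22 RPKM there and at most 0.35 in the other 8 libraries. The neurosecretory gene SCG2 had 0.85 and 0.90 RPKM, the synaptic gene SNAP25 had 0.50 and 0.59, and CGA, the common alpha chain of the pituitary glycoprotein hormones, had 0.40 and 0.58, all with at most 0.04 elsewhere. These genes were chosen after their values were seen. Both libraries belong to the high group. Without them 198 genes had an unadjusted p under 0.05 in limma, 0 passed, the heat shock and unfolded protein response list had a mean log2 fold change of 0.21 (adjusted p = 0.00322 with camera) and the T and NK cell list had -0.31 (adjusted p = 0.0354). With an estimated correlation neither list passed without these libraries (adjusted p = 0.998 for each).

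**Figure D3:**
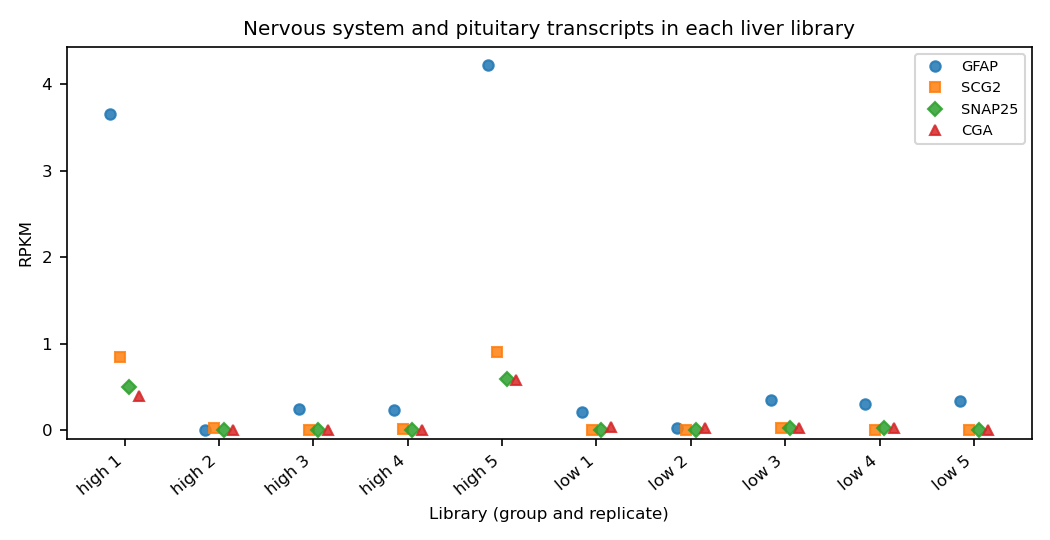
RPKM (vertical) of 4 nervous system and pituitary transcripts in each library (horizontal, group and replicate), with 1 point per gene and library. GFAP reached 3.66 and 4.22 RPKM in high replicates 1 and 5 and at most 0.35 RPKM in the other 8 libraries.

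The libraries varied more along an axis that did not follow the groups. The first principal component of the tested genes held 42.9% of the variance and the second 13.0%. High replicates 1 and 3 and low replicate 2 lay at one end of the first component, with scores of 28.6, 37.2 and 32.6, and low replicate 4 lay at the other end with -40.5. The group means were 5.37 ± 25.8 in high and -5.37 ± 26.3 in low (SD, n = 5 each), with an exact permutation p of 0.571. The acute phase list had its lowest mean level in low replicate 4, 8.21, and its highest in low replicate 2, 9.50.

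**Figure D4:**
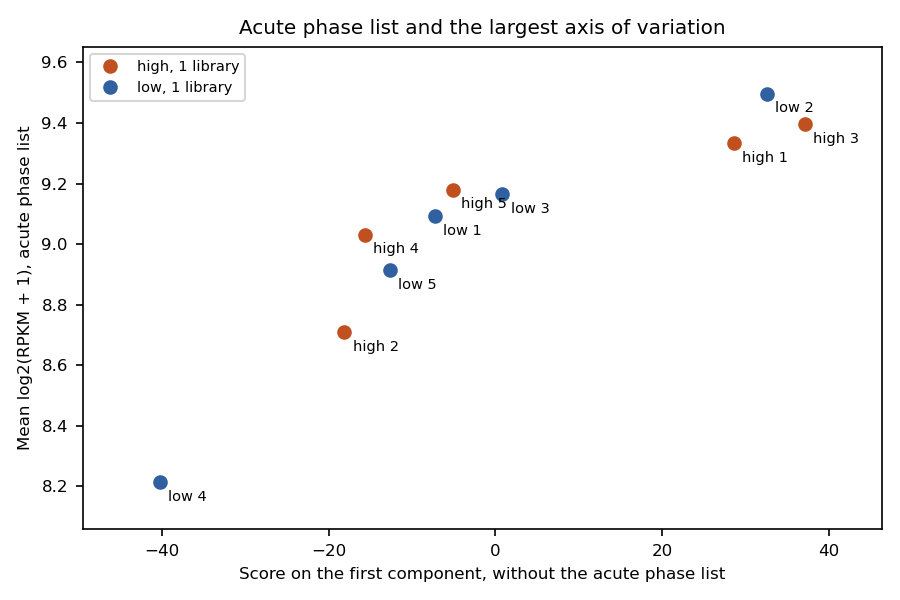
Mean log2(RPKM + 1) of the acute phase list (vertical) against the score on the first principal component computed without the genes of that list (horizontal, no unit), with 1 point per library. The level ran from 8.21 in low replicate 4 to 9.50 in low replicate 2, and the groups were spread along the whole axis.

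The authors' deposited table gave 854 genes with a p under 0.05, 395 of them with a positive and 459 with a negative fold. After a Benjamini-Hochberg adjustment of the deposited p-values the smallest was 0.563. Of the 547 tested genes with a deposited p under 0.05, 348 also had an unadjusted p under 0.05 in limma. For GPT2 the authors' deposited table gave a fold of -2.57, for FBXO39 2.21 and for ARL2BP 2.04. In 96.7% of the tested genes with a fold other than 1, a positive sign went with the higher mean log2(RPKM + 1) in low and a negative sign with the higher mean in high. What the fold was computed from is not stated in the sources used here.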

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

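The tests of the high phenotype for the nervous system transcripts, the counts of brain genes near 0 elsewhere and of genes per pair of libraries, and the reading of the brain and nerve counts by their baseline, and the limit of the T and NK cell test to single libraries, were chosen after the result was seen.

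The mean RPKM of the listed brain genes that are near 0 in most libraries was 0.179 in high replicate 1 and 0.206 in high replicate 5, and between 0.002 and 0.021 in the other 8, a signal outside the comparisons of the study, and the pair held 22 genes at least 10-fold above every other library, where the next pair of the 45 held 5. The high phenotype is left open: the level was 0.00383 on average in the other 3 high libraries and 0.021 in the highest low library, but 11 of the 20 genes behind it had been picked from this pattern. RNA or reads from brain tissue are a candidate source, but of the 10 detected brain genes not seen before the list was written 1 had its highest values in this pair. Of those 10 genes 8, among them SLC1A2 and CNP, had a median above 0.05 RPKM over the libraries, a baseline that can hide a small share. Of 20 listed brain genes near 0 elsewhere 13 had their highest values in the pair, but 11 of the 20 had been picked from this pattern. Of the 9 not seen before 2 did, GAD1 and SLC17A6, at no more than 0.05 RPKM, where chance gives 1 gene in 45. For nerve fibres inside the liver the count was 0 of 5 detected genes, of which NGFR and PRPH have a high level in all libraries, so brain tissue and nerve fibres cannot be told apart on these counts.

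Among 254 groups of 5 libraries tested for a value far from the rest, 13 stood out, where chance gives about 1 in 20. CTRL had 0.30 RPKM in high replicate 3 against 0.73 to 0.85 in the other high libraries. ARL2BP had 19.3 RPKM in high replicate 4 against at most 10.4, and 39.4 in low replicate 5 against at most 19.8. CYP7A1 had 3.02 RPKM in high replicate 2 against at most 0.86. LEPR had 39.1 RPKM in low replicate 4 against at most 4.35 in the other low libraries. CPS1, of the urea cycle, had 600.1 RPKM in low replicate 3 against at most 375. The plasma cell gene MZB1 had 2.73 RPKM in high replicate 3 against at most 1.30, and 8.89 in low replicate 2 against at most 2.30. F2 had 866 RPKM and the neutrophil gene S100A8 had 5.48 in low replicate 2, against at most 684 and 1.21. HLF had 1.58 RPKM in low replicate 5 against at least 2.74. OAS2 had 68.95 RPKM in high replicate 5 against at most 34.0. The relative depth of high replicate 2 was 0.767 against 1.0 to 1.05 in the other high libraries.

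The T and NK cell list, lower in the high group with camera's preset correlation, kept its call at that setting without any 1 library (adjusted p at most 0.0231). This argues against a single library as the reason for that call. Leaving out 1 library at a time cannot show dependence on 2. The T and NK cell level was highest in low replicates 2 and 4 (2.65 and 2.67) and was 2.26 in low replicate 1. In low replicates 3 and 5 it was 1.75 and 1.92, within the range of the high libraries (1.64 to 2.18). With an estimated correlation the list did not pass (adjusted p = 0.896 with all libraries, 0.889 to 0.982 with 1 left out). Residual blood in the samples is left open: Pearson's r of the T and NK cell level with the red blood cell level was 0.475 (permutation p = 0.166, adjusted 0.249), Spearman's rho was 0.588 (permutation p = 0.0814, adjusted 0.163), and r was 0.75 (permutation p = 0.0343, not adjusted) without the 2 libraries farthest from the median. Too few libraries were measured to decide this. Chance cannot be excluded for the lists, since 98 of 100 splits of the 10 libraries, the real one included, put at least as many lists past camera with the preset correlation as the real 2, with 11 in the highest other split. The median over the 100 splits was 6.5 lists, and all 100 had at least 1. A call at this setting, also one kept without any 1 library, therefore says little about the groups.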

How the results depend on the processing

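The covariate from the residuals and the fit without high replicates 1 and 5 were chosen after the result was seen. No gene passed in limma under any alternative run, with a smallest adjusted p of 0.226 without high replicate 5, and 0 named genes of 110 passed. The 497 genes with an unadjusted p under 0.05 became 912 with no filter (18768 genes tested), 266 with a mean of at least 5 RPKM (6124 tested), 1161 with the first residual component as covariate and 198 without high replicates 1 and 5, and lay between 280 and 815 when 1 library was left out (280 without high replicate 1, 331 without low replicate 4, 815 without low replicate 2); the cause was not tested beyond the number of genes tested. The residual component was taken from the residuals of this same comparison. It left the mean log2 fold changes of the T and NK cell list (-0.446) and the heat shock list (0.297) as they were. It could change only the spread, so the rise to 1161 is no sign of larger differences between the groups. Of the lists, 2 passed camera, and 3 did with no filter and 3 without high replicates 1 and 5. With a mean of at least 5 RPKM, which leaves the T and NK cell list under 5 members, 1 passed. With an estimated correlation 0 passed, with fry 0, and with 1 library left out 2 to 4, 4 without high replicate 5. The heat shock list had mean log2 fold changes between 0.13 (without low replicate 4, adjusted p = 0.0667) and 0.39 with 1 library left out. Of the named genes 105 kept their sign. S100A8 reversed with a pseudocount of 0.1 (0.0074), and FASN (-0.01) and HBB (0.11) without high replicates 1 and 5. With 1 library left out FASN ranged from -0.18 to 0.19, PCK1 from -0.22 to 0.22, S100A8 from -0.28 to 0.32 and STAB1 from -0.12 to 0.0095. Cell type differences near 0 did too: hepatocyte -0.15 to 0.0514, endothelial -0.0925 to 0.14, stellate -0.18 to 0.0238, cholangiocyte -0.14 to 0.0366, neutrophil -0.16 to 0.00711, and muscle 0.0613 with the median of the markers. The cause of these reversals was not tested. Count-based tests and total-count scaling were planned and not run, since the values were not counts. A surrogate variable (sva) was planned and not run either, and the first residual component was used in its place. Absolute depth is unknown, so the precision of low values is not known. Chance cannot be excluded for the 497 genes, since 32 of 100 splits, the real one included, gave as many, and the highest other split gave 3020.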

Other observations

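The tests of the acute phase list, the hepatocyte level and the mitochondrial share against the largest axis of variation, the test of the groups on it and all genes named in this part were chosen after the result was seen.

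Some genes picked for large loadings on the largest axis of variation had wide ranges over the 10 libraries. The acute phase gene ITIH4 ranged from 514 to 10831 RPKM, and the keratin genes KRT8 and KRT18 ranged from 65.0 to 1047 and from 55.4 to 744 RPKM, with the highest values in high replicate 3 and the lowest in low replicate 4. The histidine-degrading enzyme gene HAL ranged from 22.9 to 564 RPKM. In the opposite direction, the drug-metabolizing gene CYP1A2 ranged from 2.46 to 141 RPKM, CYP2A19 from 0.13 to 149, the catalase gene CAT from 170 to 1757 and the flavin monooxygenase gene FMO5 from 3.23 to 78.2. MBL2, a lectin of the complement system, had 0.67 RPKM in high replicate 1 and 7.76 in high replicate 3 and at least 48.5 in the other 8 libraries.

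The leptin receptor gene LEPR and CD207, a marker of Langerhans cells, were among 9 genes with separate levels across the libraries, of which these 2 had a symbol. CD207 had 10.6 and 13.6 RPKM in high replicate 4 and low replicate 5 and at most 0.41 in the other 8. LEPR had 37.7, 57.0 and 39.1 RPKM in high replicates 1 and 4 and low replicate 4 and at most 4.35 elsewhere. Another of the 9, ENSSSCG00000001082, had no symbol. It had 7.94 and 8.43 RPKM in high replicates 1 and 5, the libraries with the nervous system transcripts, and at most 0.05 in the other 8. No explanation was tested for any of these genes.

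Sequencing depth is argued against as the source of the largest axis of variation (42.9% of the variance) by its correlation with it (Pearson r = -0.104, permutation p = 0.763, adjusted 0.763; Spearman rho = -0.188, permutation p = 0.608, adjusted 0.73; r = 0.015 without the 2 farthest libraries). A few genes taking most of the signal is argued against too, since median scaling without the 100 most abundant genes left the order of the libraries the same (rho = 1), and the growth and fatness groups differed by less than the spread within them (exact permutation p = 0.571). Candidate explanations include differences in the acute phase response, whose list correlated with the axis computed without its genes (Pearson r = 0.901, permutation p = 1e-05, the smallest these permutations can give, adjusted 6e-05; Spearman rho = 0.964, permutation p = 5e-05, adjusted 0.00015; r = 0.883 without the 2 farthest libraries). Differences in the share of hepatocytes and in RNA quality are candidates too, since the hepatocyte level (Pearson r = -0.923, permutation p = 1e-05; Spearman rho = -0.988; r = -0.866 without the 2 farthest libraries) and the mitochondrial share (Pearson r = -0.848, permutation p = 0.00064, neither p adjusted; Spearman rho = -0.891; r = -0.801 without them) ran against the axis computed without their genes. The mitochondrial share is no direct measure of RNA quality, and it could not be set against RNA integrity, which was at hand only as a range. As a part of the summed RPKM, it also falls where other abundant transcripts rise, acute phase transcripts included. The acute phase list rose along the axis while the hepatocyte level fell. Hepatocytes make most acute phase proteins, so a change in their share alone would move both levels the same way. This argues against that share as the only source. The hepatocyte level is a mean of transcripts, so it cannot tell a lower share of hepatocytes from lower levels of these transcripts in each hepatocyte. Whether the hepatocyte level fell apart from the acute phase response was not tested. The relations of the axis with these levels and the mitochondrial share, 3 of 5 tested over the 10 libraries, were found and tested on the same data. They single out none of the explanations named, and diet and time at slaughter stay open, untested.

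The highest of the 99 other splits of the 10 libraries gave 3020 genes at an unadjusted p under 0.05, against 497 for the real groups and a median of 339.5 over all 100. Such a split points to a structure of the samples that the groups do not follow, although the highest count expected without structure was not computed. Of the 99 other splits 5 had genes past the threshold, up to 195.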
